A study of Gallus gallus with 21 samples.

How the data were processed

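The deposited values are CPM, read counts scaled to library totals, made by the authors. Per the labels' protocols, retinas were washed in RNAlater and frozen, RNA was extracted with a miRNAeasy kit, and libraries were made from total RNA with a stranded kit and depletion of ribosomal RNA. Per the submitters' processing notes, STAR and Partek were used with genome build GRCg6a, and the versions and settings of both tools are not given in the sources used here. The deposited CPM table carries 0.0001 on every value, so a gene without reads stands at 0.0001, which was subtracted. Listed genes of a library sum to 30.35 to 33.25% of the CPM scale, so the denominator took in more than the listed genes, and what else it held is not given in the sources used here. Between 93.87 and 94.58% of low values were whole multiples of a library's smallest step within a tolerance of 0.1. Whole reads are therefore not claimed, and the raw-count alternative was not run because the values are not counts. Read totals were derived from that step as estimates. The table's coordinates are given as listed, and whether they start at 0 or 1 is not given in the sources used here.

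Labels give the days of lens wear and a sample code that holds a number and a final letter, R or L. They do not explain the code, and give nothing on sex, hour of collection, batch or which samples share a bird. Tests used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust off) on log2(CPM + 1), with all 21 libraries in a single fit of 1 mean per day and 18 residual degrees of freedom. Genes with a mean of at least 1 CPM were tested, 11072 of 18631, holding 99.47% of the summed CPM. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The contrasts were day 3 minus 1, day 6 minus 3, day 6 minus 1, day 3 minus the mean of days 1 and 6, and an F test over all days. Pairwise contrasts share libraries and are not independent. Libraries with W transcripts were those with HINTW above 10 CPM.

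Before the data were seen, 40 gene lists were fixed from general knowledge: 8 of retinal cell types, 8 of other cell types, 22 of pathways, 1 of W-linked genes and 1 of candidates from the literature. Of these, 37 had enough tested genes. The lists without enough were those of red blood cells and muscle and of mitochondrially encoded transcripts, with 1, 0 and 0 tested genes, and 11 symbols were matched by an older symbol. Lists were tested with camera at a preset correlation of 0.01, adjusted over 111 tests. Beside it stand camera with an estimated correlation, counts of members adjusted over the list alone, and fry. The directional p of fry tests whether the genes of a set move on balance one way and the mixed p whether they change either way, and neither compares the set with other genes. Camera called 13 tests and fry 21, with 8 shared.

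Genes named in the results follow a rule fixed before the data were seen. For each pairwise contrast it takes the 8 risen and 8 fallen genes with the largest change among those that passed, had a symbol and had a mean log2 level of at least 3.415, the median of tested genes. It adds the 4 members with the lowest adjusted p of each list called, and 14 genes fixed by name. For the contrast of day 3 with the other days it takes 5 genes each way. Some genes that it names are not reported here. The number of libraries that show a direction counts later-day libraries beyond the mean log2 level of the earlier day.

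The procedure was tested on simulated data with 200 changed genes per comparison, 50 at each of the folds 1.25, 1.5, 2 and 3. For day 3 against 1 it recovered 28, 90, 98 and 100% of them, for day 6 against 3 42, 82, 98 and 100%, for day 6 against 1 40, 92, 98 and 100%, and for day 3 against the other days 68, 90, 100 and 100%. It called 6, 6, 9 and 17 unchanged genes, and 0 changed genes in the wrong direction. A list raised 1.25-fold was called in each pairwise comparison and 0 other lists were. The simulated genes varied independently and carried no effect of sex or code numbers. The simulation therefore cannot show how often genes or lists are called falsely where genes vary together, as they may in the real libraries. Chance was measured by regrouping libraries in 100 splits, or in all 35 splits of a day into sets of its code numbers. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.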

Results

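Retinas of White Leghorn chickens that had worn a lens of -10 dioptres were profiled by RNA sequencing. Such a lens puts the image plane behind the retina, to which a young eye responds by elongating, and the short sight that follows is called lens-induced myopia. Lenses were fitted to wild-type birds 3 days old and stayed on for 1, 3 or 6 days before the retina was taken. The data were 21 libraries of total RNA depleted of ribosomal RNA, 7 for each duration of lens wear. All samples wore lenses, and lens wear and age rose together, so every comparison lies between durations and takes in the age of the birds. The deposited table listed 18631 genes in CPM (read counts scaled to library totals). With the smallest CPM step of a library, 0.0203 to 0.0324, taken as a single read, the libraries held an estimated 30.8 to 49.3 M reads. The means were 40.8 ± 4.77 (SD), 37.5 ± 3.80 and 39.1 ± 3.27 M on days 1, 3 and 6. Of these, 9.94 to 15.3 M fell on the listed genes. Nothing in the labels says that the libraries of a day came from separate birds, so p-values measure the spread between these libraries.

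The libraries differed in transcripts of the W chromosome, and the labels do not give bird sex. Hens carry a W chromosome and cocks do not. HINTW, a multicopy W gene, stood at 101 to 147 CPM in 10 libraries and at 0.024 to 0.598 CPM in the other 11. Libraries with W transcripts made up 4 of 7 on day 1, 1 of 7 on day 3 and 5 of 7 on day 6. Between libraries with and without them, 596 of 11072 tested genes differed, among them 416 of 556 tested genes on the Z chromosome, 402 of which were lower with W transcripts. The median difference over all 556 tested Z genes was -0.41 on the log2 scale. The sample codes in the labels carry numbers whose meaning is not given. On day 1 these numbers fell into a set of 1 to 4 and a set of 12 to 14. The first held 4 libraries, 3 with W transcripts, and the second 3 libraries, 1 with W transcripts. Between both sets 352 genes differed, 97 higher and 255 lower in the set of higher numbers. With the W-linked level as a covariate 1048 genes did. That split was chosen after the data were seen, and the highest other split of these 7 libraries gave 258 genes. The fit with the covariate was not run on other splits. The chaperone gene HSP90AA1 averaged 267 ± 37.98 CPM (SD, n = 4) in the set of lower numbers and 561 ± 49.6 CPM (n = 3) in the other, and HSPA8 averaged 251 ± 77.5 and 523 ± 39.8 CPM. In the opposite direction, RBP4 averaged 237 ± 21.2 and 163 ± 16.96 CPM and PER3 77.5 ± 10.1 and 47.8 ± 2.25 CPM. The same kind of split gave 2 genes on day 3, and on day 6 limma called 0 genes, with 679 at an unadjusted p under 0.05. Camera, which ranks a list against all other genes, called the heat shock list between the day 1 sets (adjusted p = 6.33e-10, and 0.830 with an estimated correlation), where 8 of 25 members were higher and 0 lower in the set of higher numbers by limma and 16 had an unadjusted p under 0.05. It also called the ribosomal protein list there (1.55e-08, and 0.960), with 1 of 67 members higher and 9 at an unadjusted p under 0.05. Between the day 6 sets it ranked heat shock genes low (0.000398, and 0.960) and ribosomal protein genes high (0.0111, and 0.960), and between the day 3 sets rod genes high (0.0370, and 0.960). In these 3 lists limma called 0 members, with 0 of 25, 9 of 67 and 3 of 12 at an unadjusted p under 0.05.

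**Figure D1:**
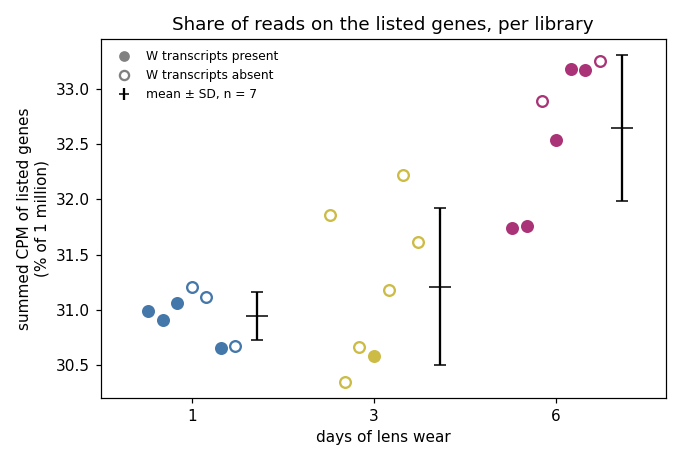
Summed CPM of the listed genes as a percentage of the whole CPM scale (y axis) in each of the 21 libraries, by days of lens wear (x axis). Points are libraries, filled where W transcripts were present, and bars the mean ± SD of 7 libraries; the share was 30.9 ± 0.216% on day 1, 31.2 ± 0.712% on day 3 and 32.6 ± 0.658% on day 6.

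Levels of 3284 of 11072 genes differed among the 3 days (limma F test, Benjamini-Hochberg adjusted p under 0.05). In the values that follow, levels are mean CPM ± SD of 7 libraries, log2 changes are of CPM + 1 with their SE, and every gene said to rise or fall did so with all 7 libraries of the later day beyond the mean of the earlier day unless another number is given.

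The first comparison was of 3 days with 1 day of lens wear. RBP4, which encodes a retinol carrier, fell from 205 ± 43.6 to 73.0 ± 16.7 CPM, a log2 change of -1.48 ± 0.15 (adjusted p = 1.52e-05). The gene lies on chromosome Z at 53612243 to 53617574 in the GRCg6a build. EGR1 (chromosome 13, 18949952 to 18952755), the immediate early transcription factor also known as ZENK, fell from 9.92 ± 2.80 to 4.21 ± 2.03 CPM (-1.13 ± 0.23, adjusted p = 0.00731). CNGA3, a subunit of the cone cyclic nucleotide-gated channel, fell from 60.96 ± 14.5 to 33.6 ± 5.90 CPM (-0.83 ± 0.12, adjusted p = 0.000312). GUCA1A, an activator of photoreceptor guanylate cyclase, fell from 70.5 ± 12.5 to 39.5 ± 4.87 CPM (-0.81, adjusted p = 0.000143). Among genes at or above the median level, the largest rise was that of NFIL3 (chromosome Z, 44356108 to 44370014), a transcriptional repressor tied to the circadian clock, at 25.5 ± 3.58 and 50.3 ± 10.7 CPM, 1.92-fold (adjusted p = 0.000105).

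In all, 366 genes changed between days 1 and 3, 185 up and 181 down, and 1990 genes had an unadjusted p under 0.05. Other genes with large rises were MICAL2, an actin-oxidising enzyme (15.8 ± 4.67 to 28.7 ± 4.48 CPM, adjusted p = 0.00139), and TPH1, which starts serotonin synthesis (10.4 ± 1.63 to 19.4 ± 3.40 CPM, adjusted p = 0.000114). The rod genes PDE6G and SLC24A1 had log2 changes of 0.87 ± 0.18 and 0.81 ± 0.14 (adjusted p = 0.0105 and 0.00194). WDCP and G0S2, an inhibitor of lipolysis, rose by 0.75 ± 0.11 and 0.70 ± 0.12 (adjusted p = 0.000211 and 0.00101). Falls were also seen for SLC25A25, a mitochondrial carrier (-0.73 ± 0.08, adjusted p = 5.44e-05), the clock gene PER3 (-0.65 ± 0.13, 0.00557), the synaptic gene NPTX2 (-0.64 ± 0.11, 0.00208), CEP164, a centriole component (-0.63 ± 0.09, 0.000211), and the kinase gene SGK1 (-0.62 ± 0.13, 0.00700).

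Of 37 gene lists fixed before the data were examined and testable, camera with a preset correlation between genes called 6 for this comparison. Of 67 cytosolic ribosomal protein genes, 19 rose and 0 fell, or 46 and 0 adjusted over the list alone (adjusted p = 1.37e-22, and 0.556 with an estimated correlation). With the W-linked level as a covariate 10 of them rose. Examples are RPL32 (0.28 ± 0.05, adjusted p = 0.00390) and RPL13 (0.30 ± 0.06, 0.00770), and RPL8 and RPL5 rose by 0.31 and 0.25 (0.00822 and 0.0105). Of 19 cholesterol synthesis genes, 4 rose and 0 fell, or 7 and 0 adjusted over the list alone (adjusted p = 2.21e-07, and 0.672 with an estimated correlation). They included FDFT1, which encodes squalene synthase, at 21.8 ± 2.84 and 31.6 ± 3.55 CPM (adjusted p = 0.000376), the mevalonate pathway gene HMGCS1 at 75.2 ± 15.0 and 108 ± 18.4 CPM (0.0108), IDI1 (0.47 ± 0.10, 0.0108) and, in 6 of 7 libraries, the cholesterol transporter gene STARD4 (0.69 ± 0.18, 0.0378).

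The other called lists were lower on day 3. Of 14 cone genes, 3 fell and 1 rose, or 5 and 1 adjusted over the list alone (adjusted p = 0.0120, and 0.801 with an estimated correlation), and 6 fell and 1 rose with the W-linked level as a covariate. Those that fell were CNGA3, the cone opsin kinase gene GRK7 (191 ± 13.6 to 129 ± 17.9 CPM, adjusted p = 0.000211) and THRB, a thyroid hormone receptor gene of cones (-0.32 ± 0.05, 0.000468). The cone transducin subunit gene GNGT2 rose by 0.40 ± 0.08 (0.00335). Of 10 immediate early genes only EGR1 passed over all genes, and 7 fell and 0 rose adjusted over the list alone (adjusted p = 0.00451, and 0.672 with an estimated correlation). DUSP6, ATF3 and FOSL2 had log2 changes of -0.28, -0.36 and -0.28 (adjusted p = 0.0622, 0.109 and 0.153). Of 25 unfolded protein and heat shock genes 0 passed the limma test, alone or over all genes, and 10 had an unadjusted p under 0.05. The list had a median of -0.12 (adjusted p = 0.00872, and 0.801 with an estimated correlation). HSPA4L, CANX, DNAJB6 and HSPH1 had changes of -0.25, -0.12, -0.11 and -0.51 (adjusted p = 0.0830, 0.139, 0.162 and 0.170). Of 6 W-linked genes 0 passed, and 0 had an unadjusted p under 0.05 (adjusted p = 0.0345, and 0.831 with an estimated correlation). Changes were -2.95 ± 1.51 for HINTW, -1.93 for SPIN1W, -1.79 for ATP5A1W and -2.56 for CHDB1 (adjusted p = 0.310, 0.316, 0.328 and 0.333), beside 4 of 7 libraries with W transcripts on day 1 and 1 of 7 on day 3.

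With the code number set as a covariate on all libraries, 13 of 13 list calls were kept, and so were all 177 results of named genes. This decides little, since libraries of higher numbers made up 3, 3 and 4 of 7 on days 1, 3 and 6. A covariate so evenly spread can hardly move differences between days, and it fits a single effect common to all days. Fits with only part of the day 1 libraries differed more. With the 4 day 1 libraries of lower numbers alone the heat shock list had a median of 0.02 and an adjusted p of 0.816, and with the 3 of higher numbers alone a median of -0.30 and an adjusted p of 1.59e-12. The call of this list also ended without day 1 replicate 5 (adjusted p = 0.0639), 6 (0.108) or 7 (0.116), which are the 3 libraries of higher numbers, and the W-linked call ended when any 1 of 9 libraries was left out. The cone and W-linked lists had adjusted p of 0.107 and 0.475 against the higher numbers alone and the immediate early list 0.0501 against the lower numbers alone. Against the higher numbers alone PER3 (-0.26, adjusted p = 0.135), PDE6G (0.80, 0.0723), STARD4 (0.62, 0.176), GNGT2 (0.32, 0.0631), RPL32 (0.24, 0.0538), RPL13 (0.20, 0.155), RPL8 (0.22, 0.118) and RPL5 (0.20, 0.0819) no longer passed, with 3 day 1 libraries in place of 7. The change of PER3 was less than that with all 7 (-0.65), while those of PDE6G, STARD4, GNGT2 and RPL32 stayed close to theirs (0.87, 0.69, 0.40 and 0.28). Against the lower numbers alone HMGCS1 (0.38, 0.0790) and IDI1 (0.32, 0.0556) did not. Of the 366 genes, 97 passed against both sets, among them RBP4 (-1.72 and -1.17), CNGA3 (-1.04 and -0.54), EGR1 (-1.14 and -1.11) and NFIL3 (1.06 and 0.78). STARD4, on chromosome Z, had a change of 0.38 with the W-linked level as a covariate (adjusted p = 0.0157), and its call ended when any 1 of 10 libraries was left out, with adjusted p up to 0.0772.

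**Figure D2:**
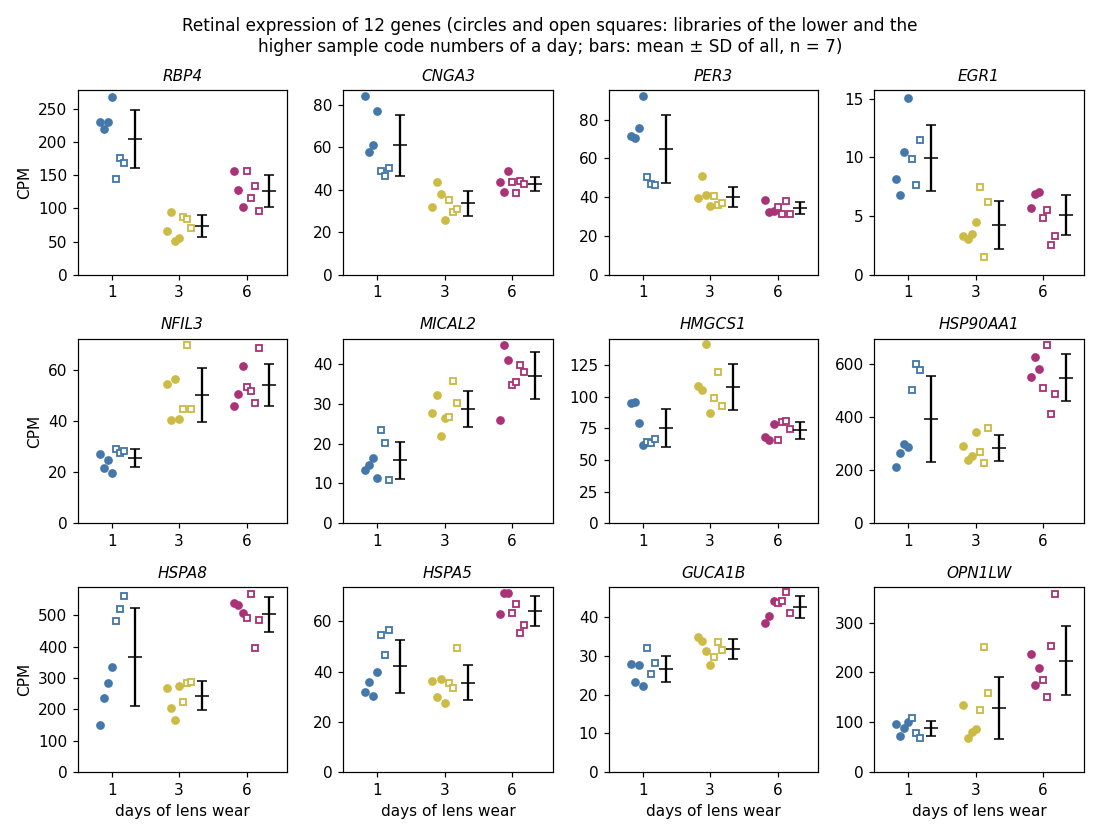
CPM of 12 genes (y axes) by days of lens wear (x axes). Circles are libraries of the lower and open squares libraries of the higher sample code numbers of a day, and bars give the mean ± SD of all 7 libraries; RBP4 fell from 205 to 73.0 CPM between days 1 and 3, and HSP90AA1 lay higher in the 3 open squares of day 1 (561 CPM) than in the 4 circles (267 CPM).

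The second comparison was of 6 days with 3 days of lens wear. Chaperone genes rose: HSPA8 went from 244 ± 47.3 to 503 ± 55.5 CPM (1.06 ± 0.22, adjusted p = 0.00210) and HSP90AA1 from 284 ± 50.5 to 550.0 ± 88.7 CPM (0.95 ± 0.20, 0.00209). HSPA5 (chromosome 17, 9890854 to 9894907), the chaperone BiP of the endoplasmic reticulum, went from 35.6 ± 6.99 to 64.3 ± 5.97 CPM (0.85 ± 0.13, 0.000307). The red cone opsin gene OPN1LW rose too, from 129 ± 62.8 to 224 ± 68.7 CPM (0.87 ± 0.23, 0.01003). RSRP1 rose from 67.2 ± 22.2 to 166 ± 27.004 CPM and EGLN3, a prolyl hydroxylase of the hypoxia response, from 9.92 ± 2.96 to 22.3 ± 10.2 CPM (adjusted p = 0.00154 and 0.00387). Some of these genes differed as much within day 1, at the same lens duration. There the set of higher code numbers exceeded the lower on the log2 scale by 1.11 for HSPA8, 1.08 for HSP90AA1, 0.60 for HSPA5 and 1.37 for RSRP1. EGLN3 and OPN1LW had differences of 0.51 and -0.08.

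In all, 2524 genes changed between days 3 and 6, 2143 up and 381 down, and after median-of-ratios scaling 1849 genes changed, 920 up and 929 down. Among the rises were ARHGEF11 (0.94 ± 0.18, adjusted p = 0.00148), RPS19 (0.94 ± 0.26, 0.0132), the cochaperone gene DNAJA1 (0.88 ± 0.20, 0.00473) and, in 5 of 7 libraries, ARL2BP (0.87 ± 0.29, 0.0349). The call of ARL2BP ended when any 1 of 8 libraries was left out (adjusted p up to 0.0763) and after median-of-ratios scaling (0.79, 0.0657). The 8 named genes with the largest falls all lay on chromosome Z, beside 1 of 7 libraries with W transcripts on day 3 and 5 of 7 on day 6: STARD4 (-0.74 ± 0.18, 0.00644), CNTNAP4 (-0.71, 0.00113), ERCC8 (-0.70, 0.0115), ANKRD31 (-0.70, 0.000270), ATP5I (-0.69, 0.0128), ZNF131 (-0.68, 0.00759), the cholesterol efflux gene ABCA1 (-0.65, 0.00192) and, in 6 of 7 libraries, HINT1Z (-0.63, 0.0345). With the W-linked level as a covariate, STARD4, CNTNAP4 and ERCC8 had changes of -0.32, -0.40 and -0.24. ATP5I (-0.24, adjusted p = 0.0617), ZNF131 (-0.38, 0.0657) and HINT1Z (-0.13, 0.337) no longer passed with it, while ANKRD31 (-0.64, 0.00146) and ABCA1 (-0.72, 0.00301) did. How the authors' counting treated any reads shared by HINT1Z and HINTW is not given in the sources used here. In the day 3 libraries without W transcripts HINT1Z stood at 34.34 to 51.46 CPM and HINTW at 0.0243 to 0.162 CPM, so few HINT1Z reads were counted as HINTW there. The call of HINT1Z also ended when any 1 of 10 libraries was left out (adjusted p up to 0.0712). Of 556 tested Z genes, 100 fell and 16 rose, and with that covariate 28 fell and 71 rose.

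Camera called 3 lists. Of 25 unfolded protein and heat shock genes, 19 rose and 0 fell, or 20 and 0 adjusted over the list alone (adjusted p = 4e-07, and 0.672 with an estimated correlation), and 16 rose and 0 fell after median-of-ratios scaling. Besides the chaperones above they included PDIA6, a protein disulfide isomerase (0.58 ± 0.08, adjusted p = 0.000138), HSPA2 (1.04 ± 0.18, 0.000760) and the mitochondrial chaperonin gene HSPD1 (0.51 ± 0.10, 0.00108). Of 22 glycolysis genes, 9 rose and 0 fell, or 11 and 1 adjusted over the list alone (adjusted p = 0.0270, and 0.831 with an estimated correlation), and 5 rose and 1 fell after median-of-ratios scaling. The hexokinase genes HK2 and HK1 went from 91.1 ± 20.7 to 158 ± 23.3 CPM and from 114 ± 8.06 to 144 ± 8.57 CPM (adjusted p = 0.000574 and 0.000446), and PGK1 and ALDOC rose by 0.34 ± 0.06 and 0.46 ± 0.11 (0.000419 and 0.00613). The glycolysis call ended without day 3 replicate 3 (0.0593) or day 6 replicate 6 (0.0722), or with only the lower numbers of day 1 in the fit (0.0610). Of 19 cholesterol synthesis genes, 5 fell and 0 rose, or 6 and 0 adjusted over the list alone (adjusted p = 3.27e-06, and 0.731 with an estimated correlation). HMGCS1 returned from 108 ± 18.4 to 73.5 ± 6.56 CPM (adjusted p = 0.00227). INSIG1, a brake on sterol synthesis, fell from 50.6 ± 13.8 to 33.5 ± 1.64 CPM (0.0174).

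**Figure D3:**
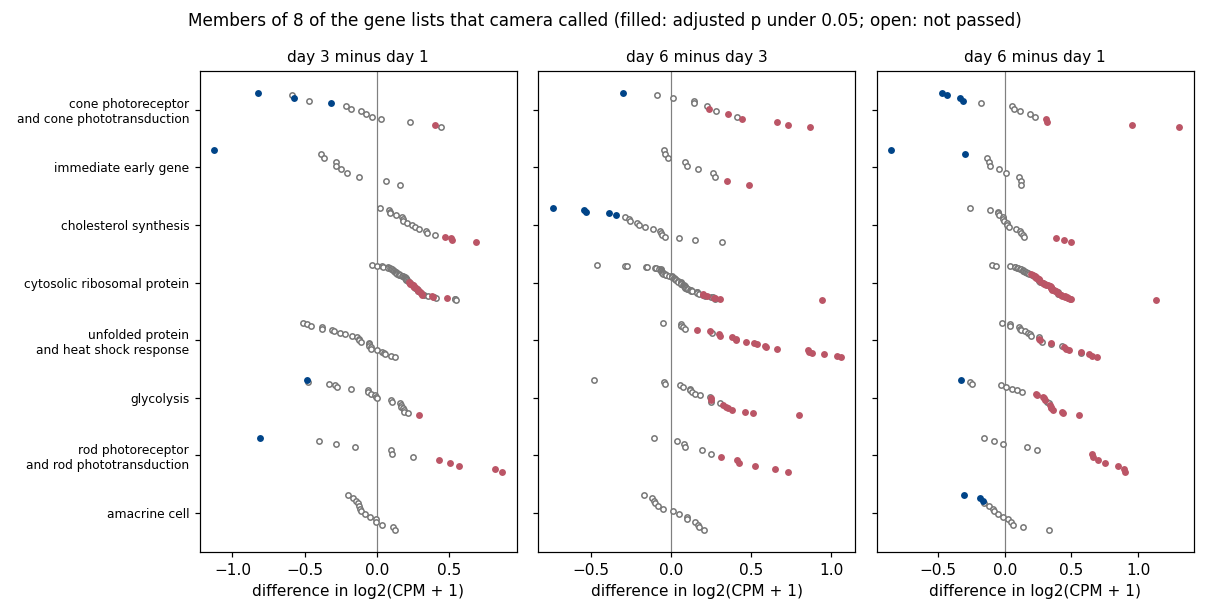
Log2 change of CPM + 1 (x axis) of each tested member of the gene lists that camera called, the W-linked list left out (y axis), in the 3 comparisons of days. Points are genes, filled where the adjusted p was under 0.05 (red risen, blue fallen) and open otherwise; 19 of 25 unfolded protein and heat shock genes rose between days 3 and 6.

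The third comparison was of 6 days with 1 day of lens wear. The red cone opsin gene OPN1LW went from 87.7 ± 15.1 to 224 ± 68.7 CPM, 2.48-fold (1.31 ± 0.23, adjusted p = 0.000447). The green cone opsin gene OPN1MSW went from 40.0 ± 6.96 to 79.9 ± 23.1 CPM (0.96 ± 0.15, 0.000168). PRDM1 (chromosome 3, 68347905 to 68446169), a transcription factor of photoreceptor fate, rose from 17.009 ± 2.40 to 39.4 ± 3.79 CPM (1.17 ± 0.11, 1.81e-06). MICAL2 rose to 37.1 ± 5.94 CPM (1.21 ± 0.15, 1.57e-05). PER3 fell from 64.8 ± 17.5 to 34.2 ± 3.11 CPM (-0.86 ± 0.13, 0.000107). KLF9, a transcription factor gene induced by thyroid hormone and glucocorticoids, fell from 92.4 ± 8.14 to 58.0 ± 7.51 CPM (-0.67 ± 0.08, 2.03e-05).

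In all, 2691 genes changed between days 1 and 6, 2197 up and 494 down, and after median-of-ratios scaling 1941 genes changed, 901 up and 1040 down. NFIL3, EGLN3, RPS19 and RSRP1 also rose (1.06 ± 0.12, 1.19 ± 0.23, 1.13 ± 0.26 and 1.01 ± 0.26; adjusted p = 9.25e-06, 0.00113, 0.00381 and 0.00888). Falls were seen for the lectin gene CLEC3A (-0.82 ± 0.14, adjusted p = 0.000415), RBP4 (-0.69 ± 0.15, 0.00327), PDGFRL (-0.63 ± 0.14, 0.00230), DACT1, an antagonist of WNT signalling (-0.61 ± 0.15, 0.00671), the ion exchanger gene SLC24A4 (-0.57 ± 0.09, 0.000176), CNTNAP4 (-0.53 ± 0.13, 0.00741) and EGR1 (-0.85 ± 0.23, 0.0107). Against the day 1 libraries of higher code numbers alone, RSRP1 (0.23, adjusted p = 0.514), RPS19 (0.71, 0.145), RBP4 (-0.38, 0.174), PDGFRL (-0.42, 0.0944), DACT1 (-0.22, 0.345) and EGR1 (-0.84, 0.0719) no longer passed. PER3 and CLEC3A passed against both sets but with different values, -0.47 and -0.46 against the higher numbers and -1.15 and -1.08 against the lower. The count against the higher numbers alone was 1505, of which 1378 rose, and 720 of the 2691 genes passed against both day 1 sets.

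Camera called 4 lists. Of 12 rod genes, 7 rose and 0 fell, or 8 and 0 adjusted over the list alone (adjusted p = 0.00451, and 0.801 with an estimated correlation). They included GUCA1B, an activator of guanylate cyclase, from 26.6 ± 3.30 to 42.6 ± 2.85 CPM (adjusted p = 7.13e-06), the rod channel gene CNGB1 (0.85 ± 0.11, 2.53e-05) and SLC24A1 (0.89 ± 0.14, 0.000229). Of 67 ribosomal protein genes, 40 rose and 0 fell, or 46 and 0 adjusted over the list alone (adjusted p = 1.53e-09, and 0.731 with an estimated correlation), and 26 rose and 0 fell after median-of-ratios scaling. RPL13, RPLP0, RPL4 and RPL32 rose by 0.50, 0.45, 0.37 and 0.34 (adjusted p = 1.93e-05, 2.03e-05, 8.08e-05 and 0.000173). Of 14 amacrine cell genes, 3 fell and 0 rose, or 3 and 1 adjusted over the list alone (adjusted p = 0.0142, and 0.672 with an estimated correlation), and 6 fell and 0 rose after median-of-ratios scaling. Among those that fell were the inhibitory transmitter transporter gene SLC32A1 (-0.30 ± 0.08, adjusted p = 0.00743) and the choline transporter gene SLC5A7 (-0.16 ± 0.06, 0.0487). CHAT had a change of 0.33 ± 0.12 (0.0523). Against the higher code numbers alone SLC32A1 no longer passed (-0.13, 0.244), nor did SLC5A7 against the lower numbers alone (-0.13, 0.210), when any 1 of 16 libraries was left out (up to 0.106) or with the W-linked level as a covariate (-0.16, 0.0523).

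The remaining list was that of unfolded protein and heat shock genes, of which 10 rose and 0 fell, or 12 and 0 adjusted over the list alone (adjusted p = 0.00609, and 0.801 with an estimated correlation), and 6 rose and 0 fell after median-of-ratios scaling. CALR, PDIA6, HSPA5 and HSPD1 rose by 0.69 ± 0.12, 0.45 ± 0.08, 0.63 ± 0.13 and 0.46 ± 0.10 (adjusted p = 0.000548, 0.000634, 0.00206 and 0.00206). This call too differed with part of the day 1 libraries. Against the lower numbers alone 16 genes rose, with a list median of 0.42 (adjusted p = 3.34e-07), and against the higher numbers alone 3 rose, with a median of 0.10 and an adjusted p of 0.949 in the other direction relative to other genes. Against the latter HSPA5 and HSPD1 did not pass (0.29, 0.143 and 0.19, 0.167), and CALR and PDIA6 were at 0.36 and 0.26 (0.0496 and 0.0486). Across all 3 comparisons 0 of the 13 list calls held with an estimated correlation, where limma's camera gave adjusted p from 0.556 upward, while 10 of 13 held with the preset correlation whichever library was left out.

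The last comparison set the day 3 level against the mean of days 1 and 6. It called 935 genes, 153 higher and 782 lower on day 3, and after median-of-ratios scaling 764 genes, 325 higher and 439 lower. Among genes at or above the median level, RBP4 was lowest relative to the other days (-1.14 ± 0.13, adjusted p = 0.000117), followed by RSRP1 (-0.83 ± 0.23, 0.0278), ARL2BP (-0.83 ± 0.25, 0.0447), GUCA1A (-0.77 ± 0.10, 0.000139) and HSPA8 (-0.77 ± 0.19, 0.0157). The highest on day 3, all on chromosome Z, were STARD4 (0.71 ± 0.16, 0.00879), ANKRD31 (0.55 ± 0.09, 0.00147), ADAMTS12 (0.55 ± 0.13, 0.0104), NUP155 (0.55 ± 0.14, 0.0218) and ATP5I (0.55 ± 0.17, 0.0424). For STARD4, NUP155 and ATP5I, 6 of 7 day 3 libraries lay above the mean of the other days. With the W-linked level as a covariate STARD4, ADAMTS12, NUP155 and ATP5I had values of 0.35, 0.31, 0.23 and 0.16 (adjusted p = 0.00998, 0.0468, 0.0850 and 0.217). RSRP1 and ARL2BP kept values of -0.81 and -0.92, with adjusted p of 0.0594 and 0.0512. The count fell to 444, 548 and 524 without day 3 replicate 2, 3 or 5. RSRP1 no longer passed when any 1 of these was left out (adjusted p = 0.0666, 0.0682 and 0.0793), nor did NUP155 without replicate 2 (0.0554) or 5 (0.0556), and the calls of ATP5I and ARL2BP ended when any 1 of 15 and 16 libraries was left out (up to 0.105 and 0.0936). ARL2BP also no longer passed after median-of-ratios scaling (-0.79, 0.0604) or with only the lower day 1 numbers in the fit (-0.80, 0.0810), though its value changed little, and ATP5I with only the higher ones (0.47, 0.0944). RSRP1 stood at -0.54 with only the lower numbers and at -1.22 with only the higher ones.

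Of 98 list tests that camera did not call, 14 had an unadjusted p under 0.05. Rod genes stood at 5 risen and 1 fallen between days 1 and 3 (camera adjusted p = 0.125) and 6 risen and 0 fallen between days 3 and 6 (0.0818), or 5 and 1 after median-of-ratios scaling. The latter was called with the W-linked level as a covariate (0.0373, 7 risen and 0 fallen) and after quantile normalization (0.00931). Cone genes had 6 risen and 1 fallen between days 3 and 6 (0.271), or 4 and 1 after median-of-ratios scaling, and 4 of each between days 1 and 6 (0.593). With the covariate 10 rose and 1 fell between days 3 and 6, and camera called the list (0.0244). Quantile normalization left it at 0.0532. Glycolysis genes had 12 risen and 1 fallen between days 1 and 6 (0.0599, and 0.0197 after quantile normalization), or 6 and 2 after median-of-ratios scaling. Camera did not call the retinal cell type lists of bipolar cells, horizontal cells, ganglion cells and Müller glia in any comparison. Their lowest adjusted p was 0.0818, for ganglion cells between days 1 and 3. With the W-linked level as a covariate camera ranked that list low (0.0354), though limma called 0 of its 14 members (5 at an unadjusted p under 0.05). Fry called the horizontal cell list up between days 3 and 6 (0.00805), where 2 of 8 members rose and 0 fell by limma. Lists of 6 other cell types (pigment epithelium, vessels, connective tissue, lens, microglia and myelin) gave 0 calls by camera in 18 tests, none of them with an unadjusted p under 0.05, and 0 by fry. They held 3 to 6 tested genes each, so a lack of calls says little. By limma 2 connective tissue genes rose and 0 fell between days 3 and 6, and 1 pigment epithelium gene rose and 1 fell. Between days 1 and 6, 1 connective tissue and 1 microglia gene rose and 1 pigment epithelium gene fell. Of 34 tested genes named in work on myopia and eye growth, 3 fell and 0 rose between days 1 and 3, 6 rose and 0 fell between days 3 and 6, and 2 rose and 2 fell between days 1 and 6, or 5 and 2, 0 and 4, and 2 and 2 fallen and risen adjusted over the list alone (camera adjusted p of 0.595, 0.635 and 0.245). After median-of-ratios scaling 3 of them rose and 3 fell between days 3 and 6.

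Genes fixed by name for their part in eye growth included several that did not pass in any comparison. GCG, which encodes glucagon, had changes of -0.14, 0.03 and -0.10 in the 3 comparisons (adjusted p = 0.461, 0.825 and 0.438). Proenkephalin (PENK) had 0.01, -0.03 and -0.03 (0.963, 0.736 and 0.811) and neurotensin (NTS) 0.04, -0.05 and -0.01 (0.794, 0.634 and 0.958). The retinoic acid synthesis gene ALDH1A2 had 0.32, -0.15 and 0.18 (0.211, 0.454 and 0.353) and glutamine synthetase of Müller glia (GLUL) -0.16, 0.15 and -0.01 (0.432, 0.318 and 0.939). EGR1 had a change of 0.27 ± 0.23 between days 3 and 6 (0.406), and OPN1LW had a change of 0.44 ± 0.23 between days 1 and 3 (0.317). FOS, VIP, TH, BMP2, BMP4 and UTS2B averaged 0.815, 0.502, 0.354, 0.773, 0.0622 and 0.524 CPM over all libraries, under the minimum of 1 CPM, and were not tested.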

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

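The rule for single-library values was fixed before the data were seen, but some genes it was applied to, RP1 among them, were chosen afterwards. The tests of code numbers, W transcripts, gene span and the Z chromosome were chosen, and their predictions written, after results were seen. The W-linked level as a covariate for gene counts was itself a setting fixed beforehand, and only its use as a test here came after. Levels of 103 named genes and 9 lists, summed CPM, total reads and RN7SL1 were searched for a library standing apart from the 6 others of its day, by the ratio of its gap to the range of the day (Dixon's test). It marked 23 of 345 groups, 6.7%, where chance alone marks about 1 in 20, and 21 of the 23 are given here. Day 3 replicate 4, the only day 3 library with W transcripts, stood apart in W-linked genes, with ATP5A1W at 15.07 CPM (others 0 to 0.0999), CHDB1 at 72.7 (0.0243 to 0.0787), HINTW at 116.8 (0.0243 to 0.162), SPIN1W at 21.34 (0 to 0.0649) and a W-linked list mean of 4.826 on the log2 scale (0.0231 to 0.0815). It was low in Z genes, with ATP5I at 11.71 (18.44 to 23.57), ERCC8 at 8.457 (all others at least 17.45), HINT1Z at 19.35 (34.34 to 51.46), NUP155 at 9.522 (16.71 to 19.42) and STARD4 at 40.97 CPM (73.59 to 90.61). Day 6 replicate 7 was high in CHAT at 7.562 (4.713 to 5.764) and GLUL at 796.5 (477.8 to 594.7). Day 1 replicate 4 was high in FOSL2 at 8.004 (4.356 to 5.684), SLC24A4 at 391.4 (270.1 to 314.1) and the amacrine list mean at 4.834 (4.661 to 4.727), and day 1 replicate 3 in the rod list mean at 5.2 (4.903 to 5.014). Day 3 replicate 5 was high in PDGFRL at 19.1 (9.672 to 12.91) and RP1 at 236.2 (177.4 to 197.6), and day 3 replicate 2 in PER3 at 50.67 (35.54 to 41.26). Day 6 replicate 3 was high in PENK at 16.28 (14.48 to 15.12), and day 1 replicate 5 was high in TPH1 at 13.97 (9.309 to 10.42). No library was removed.

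Chance as the source of the gene counts was tested by regrouping the libraries. For day 3 against 1 the real count of 366 was reached by 1 of 100 splits, the real one, and the highest other split gave 35. For day 6 against 3 it was 1 of 100 (2524, highest other 666), for day 6 against 1 also 1 of 100 (2691, 747), for the F test 1 of 100 (3284, 1629) and for day 3 against the other days 1 of 100 (935, 1). Chance can be excluded for these groupings to the depth of 100 splits. The grouping by W transcripts, counted on genes off W because a W gene defined it, was 1 of 100 (569, 3). Of these genes 416 lie on Z, whose copy number goes with sex, so for them the outcome was fixed by the grouping. The 153 genes off both Z and W were not counted alone in the splits. They outnumber the 3 genes off W of the highest other split. The many Z and W genes eased the adjusted threshold in the real grouping alone, however, so chance is not excluded for these 153. The sets of code numbers gave 352 genes on day 1, reached by 1 of 35 splits, with 258 in the highest other. That split was tried because of what the data showed, so its rank does not exclude chance. On day 3 the sets gave 2 genes, reached by 4 of 35 splits (highest other 2), so chance cannot be excluded. On day 6 they gave 0 by limma (679 at an unadjusted p under 0.05), which all 35 of 35 splits reach, so that count says nothing about chance.

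Most genes that changed between days 3 and 6 rose, 84.9%. A scaling factor per library might produce such a lean, and after quantile normalization 1818 genes were called, of which 1273 were among the 2524, so scaling does not account for all calls. Their share of rises, 49.1%, decides nothing because that step fixes it near an even split. Unequal numbers of libraries with W transcripts did not account for it, as 84.3% rose with the W-linked level as a covariate. Gene span alone did not either, as at least 79.3% rose in each of 5 bins. The share did fall with span, from 91.5% in the bin of the shortest genes to 79.3% in that of the longest. The share of listed genes in the CPM scale was higher on day 6 (32.6%) than on day 3 (31.2%). That lifts listed genes in CPM on balance, so the lean goes with this rise of share. What raised it, and whether the retina's RNA rose as a whole, cannot be told from CPM, which is scaled to library totals. Age and lens wear cannot be told apart either, and unlensed birds of each age would separate them.

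On day 3, 870 genes off chromosomes Z and W stood apart from the other days, 776 of them lower, or 431 lower and 235 higher after quantile normalization, so how far they lean down depends on the scaling. Sex makeup could explain this if the calls vanished with the W-linked level as a covariate, but 958 were called, 664 of the 870 in the same direction. A scaling factor could if they vanished after quantile normalization, but 666 were called, 524 of the 870 in the same direction. For Z genes the sex makeup is a likely source, since 59 were higher on day 3 and 12 were with the covariate. The count over all genes fell to 444, 548 and 524 without day 3 replicate 2, 3 or 5, so these libraries carry much of it. Collection of the days in separate sessions might give the same pattern, and dates of collection would test it.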

How the results depend on the processing

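Settings with W transcripts as a filter or combined with quantile normalization, with Z and W genes left out, or using code numbers were chosen after the data were seen, as was the W-linked covariate for gene lists, and the others before. Between days 1 and 3, the 366 genes became 230 with only the compared days in the fit, 69 with a log2 change of at least 0.5, 576 with the W-linked level as a covariate and quantile normalization, 125 in libraries without and 16 in libraries with W transcripts, and 626 with the day 1 libraries of higher code numbers left out. Between days 3 and 6, 2524 became 283 with that fold, 91 without and 57 with W transcripts. Between days 1 and 6, 2691 became 282 with that fold, 24 without and 1576 with W transcripts, and 1505 with the day 1 libraries of lower code numbers left out. The F test gave 209 and 1036 genes without and with W transcripts in place of 3284. For day 3 against the other days, 935 became 84 with that fold, 203 without and 15 with W transcripts. Fits restricted by W transcripts hold fewer libraries, and a direct test by limma of whether the change between days 1 and 6 differs with W transcripts called 0 genes (375 at an unadjusted p under 0.05), and for the other moves the cause was not tested. Leaving out 1 library gave 261 to 382, 1902 to 2920 and 2217 to 2859 genes in the pairwise comparisons, 2753 to 3604 in the F test and 444 to 1075 for day 3 against the other days, where omission of day 3 replicate 2, 3 or 5 gave 444, 548 and 524. List calls, 13, ranged from 11 to 15 and named-gene calls, 98, from 90 to 97. List calls were 0 with an estimated correlation and 21 with fry, and named-gene calls were 32 without and 36 with W transcripts. Directions turned for the unfolded protein and heat shock list between days 1 and 3 with the day 1 libraries of higher code numbers left out (adjusted p = 0.816) and between days 1 and 6 with those of lower numbers left out (0.949), while that of the W-linked list between days 1 and 3 turned with the W-linked level as a covariate (0.982), which that setting fixes by construction. In 177 named gene comparisons 0 calls turned direction. The other 10 settings fixed beforehand gave 338 to 464, 1685 to 3424 and 1803 to 2997 genes in the pairwise comparisons. At the estimated depth of these libraries 3 reads are worth 0.0609 to 0.0973 CPM, so the minimum of 1 CPM and not depth left genes untested. No paired analysis was possible because the labels give no shared replicate numbers.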

Other observations

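The genes in the following paragraphs were chosen after their values were seen, and so were the tests of the clock genes. Of 16 genes of the outer segment and its cilium, 3 rose and 0 fell between days 1 and 3, or 3 and 3 with the W-linked level as a covariate, and 3 rose and 1 fell between days 3 and 6. Between days 1 and 3, the retinoid transporter gene ABCA4 rose from 179.9 ± 16.8 to 237 ± 7.67 CPM (SD, n = 7, adjusted p = 0.000211) and TULP1 by 0.42 (0.00236). Between days 3 and 6, AIPL1, a chaperone of phosphodiesterase, rose from 7.45 ± 1.64 to 13.3 ± 1.72 CPM (0.000729) and RP1L1 by 0.46 (0.00183), while the axoneme gene RP1 fell by 0.40 on the log2 scale (0.00139). The list was not called by camera, whereas its fry mixed p was 4.35e-11 between days 1 and 3. Among genes of the hypoxia response, PFKFB3, which drives glycolysis, rose from 57.2 ± 7.42 to 81.8 ± 10.03 CPM between days 3 and 6 (0.000512) and the collagen hydroxylase gene P4HA1 by 0.45 (0.00492). That list had 7 risen and 0 fallen genes between days 3 and 6 (camera 0.521, fry 0.0027), or 3 and 2 after median-of-ratios scaling. In the matrix, LAMC1 rose by 0.56 (0.00161) and TIMP2 by 0.43 (0.0115) between days 3 and 6, where 5 of 22 matrix genes rose and 0 fell (camera 0.862, fry 0.00805). Of all 11072 tested genes 2143 rose and 381 fell there, a lean that fry does not take out. Among dopamine genes DRD4 rose by 0.39 (0.0137) and PTS by 0.40 (0.00177), while DRD5 fell by 0.25 (0.0281). That list had 3 risen and 1 fallen of 11 (camera 0.955), or 2 and 2 after median-of-ratios scaling.

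Clock genes moved in opposite directions between days 1 and 3. ARNTL rose from 25.4 ± 4.23 to 40.8 ± 4.45 CPM (adjusted p = 0.000135) and its partner gene NPAS2 by 0.57 (0.00278), while PER2 fell from 182 ± 25.4 to 127 ± 11.1 CPM (0.000745), CRY2 by 0.38 (0.000376), NR1D2 by 0.33 (0.000924) and BHLHE41 by 0.62 (0.00139). PER2 and CRY2 rose again between days 3 and 6, by 0.46 (0.000750) and 0.36 (0.000391). Of 21 clock and melatonin genes, 5 rose and 5 fell between days 1 and 3 (camera 0.966, fry mixed 1.12e-11).

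A different hour of collection on each day might place the retinas at different phases of the clock. It predicts that genes of the activator phase (ARNTL, CLOCK, NPAS2, NFIL3) and of the repressor phase part, and between days 1 and 3 their mean changes differed by 0.92 on the log2 scale. That value restates what was seen in these genes, so it decides nothing about the hour of collection. The code number sets of day 1 could not produce this alone, since the lower difference with either set was 0.76, nor could sex makeup, since the difference was 0.94 with the W-linked level as a covariate. A change of the clock with lens wear or age would give the same values. Hours of collection for each retina, or retinas of lensed and unlensed birds taken at a fixed hour on each day, would tell these apart.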
